A study of Homo sapiens with 9 samples.

How the data were processed

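RNA from HT-29 cells, an established line of human colon adenocarcinoma with epithelial morphology, was measured on Affymetrix whole-transcript gene arrays. The 9 arrays fall into 3 groups of 3: untreated cells (given the vehicle, per the labels' treatment protocol), cells given rosemary extract, and cells given carnosic acid. All were harvested after 24 h. The series' design text calls the 3 arrays of a group biological replicates, and no shared culture day is named. The concentrations of extract and carnosic acid are not given in the sources used here, so the treatments are set side by side without a matched dose.

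The deposited values are RMA expression values on a log2 scale, made with the oligo package in R per the labels. RMA corrects background, brings the arrays to a common distribution and summarises the probes of a row. Versions and the array annotation used by the authors are not given in the sources used here. The log2 scale was taken from the values. Array medians over all 53617 rows lay between 4.82 and 4.90. RMA compresses large fold changes and gives no detection call, so a low value cannot be told from background. Quantile-type normalization also assumes that most genes do not shift together. The number of arrays, 3 per group, limits the precision.

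Rows were named through the platform's annotation, an older table whose Entrez identifiers were looked up in a current RefSeq gene table. All 16098 identifiers matched and 0 symbols changed. Of the rows, 16098 had 1 gene symbol, 0 had several and 37519 were unnamed in the annotation used here, which includes rows of several well-known genes. For each of 14884 genes the row with the highest mean over the 9 arrays was kept (779 genes had over 1 row). The lowest 25% by mean, 3721 genes under a log2 level of 4.50, were left out as dim, which left 11163 genes. No pair of arrays held identical values (0 pairs). Arrays of 1 group correlated at 0.992 or above.

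Group means were fitted to all 9 arrays at once with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 6 residual degrees of freedom). Both treatments were compared with untreated cells and with each other, two-sided. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the 11163 genes, and a gene is called at an adjusted p under 0.05. Fold changes are differences of mean log2 values, with limma's standard error (SE). A moderated F test asked whether any group differed. Simulated unchanged groups against the same controls (100 draws) gave the chance overlap and correlation of the comparisons, which share their untreated arrays.

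Pathway and cell type lists were written before the data were examined. They covered the unfolded protein response, amino acid and tRNA charging genes, sterol, LXR and fatty acid genes, NRF2 targets, heat shock proteins, metallothioneins, xenobiotic metabolism, cell cycle, p53 targets, the BCL2 family, autophagy, glycolysis, respiration, Wnt, ERK, NF-kB, interferon, ribosomal and mitochondrial genes. Cell type lists covered absorptive, goblet and enteroendocrine cells, fibroblasts, leukocytes and hepatocytes. A list needed 3 tested members, which 28 lists had. The mitochondrially encoded list had 0 tested members, xenobiotic metabolism 1 and fibroblast 2. Counts below are out of tested members, often only part of a list as written. Tested were 10 of 26 NRF2 targets, 8 of 18 amino acid genes, 5 of 14 p53 targets and 8 of 27 respiratory chain genes. All 12 aminoacyl-tRNA synthetases and all 20 G1/S genes were tested. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. With an estimated correlation camera also tests on the 6 residual degrees of freedom, which gives higher p-values at the same correlation. Camera compares a list with the other genes, and fry asks whether a list moves on balance in 1 direction.

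Named genes follow a rule also written before the data were examined. For each treatment it takes the 8 largest rises and 8 largest falls among called genes whose treated arrays lie apart from the untreated ones (5 and 5 between the treatments), leaving out uncharacterised loci and small RNAs. It adds a set of unfolded protein response, sterol and electrophile response genes whatever their values, and up to 4 members of each list with the smallest p. Genes outside it are said to be so.

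On simulated data with 200 changed genes among 11163, the fit for rosemary extract against untreated recovered 18.8% of genes changed 1.2-fold, 94% of those changed 1.5-fold and 100% of those changed 2-fold. For carnosic acid against untreated the shares were 14.8%, 90.4% and 100%, and between the treatments 20.8%, 90.4% and 99.6%. False calls made up 5.44%, 6.03% and 5.13% of the calls. The simulated genes were independent, and far fewer changed than were called in the real comparisons, so these shares need not carry over to them. In the simulated carnosic acid comparison camera found the shifted list in 20 of 20 draws. Every member of that list was shifted by 0.3 (log2), so this does not show how camera performs on lists whose genes move together or both ways. Alternatives covered the dim filter, scaling, probe choice, unnamed rows, variance model, array weights, the arrays fitted, a replicate block, leaving out each array and a 2-fold minimum.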

Results

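HT-29 colon cancer cells were profiled after 24 h with the vehicle, with rosemary extract, a polyphenol-rich plant extract, or with carnosic acid, a phenolic diterpene found in rosemary. Each group had 3 arrays. The study set out to describe the response of these cells to rosemary polyphenols, with the unfolded protein response and cholesterol metabolism named in its title. Lists for those themes are therefore not independent evidence of their direction. The first principal component held 68.1% of the variance and placed rosemary extract arrays (21.8 to 28.7) opposite untreated arrays (-25.3 to -23.9), with carnosic acid arrays between them (-6.02 to 2.79). The moderated F test called 3972 of 11163 genes (35.6%).

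**Figure D1:**
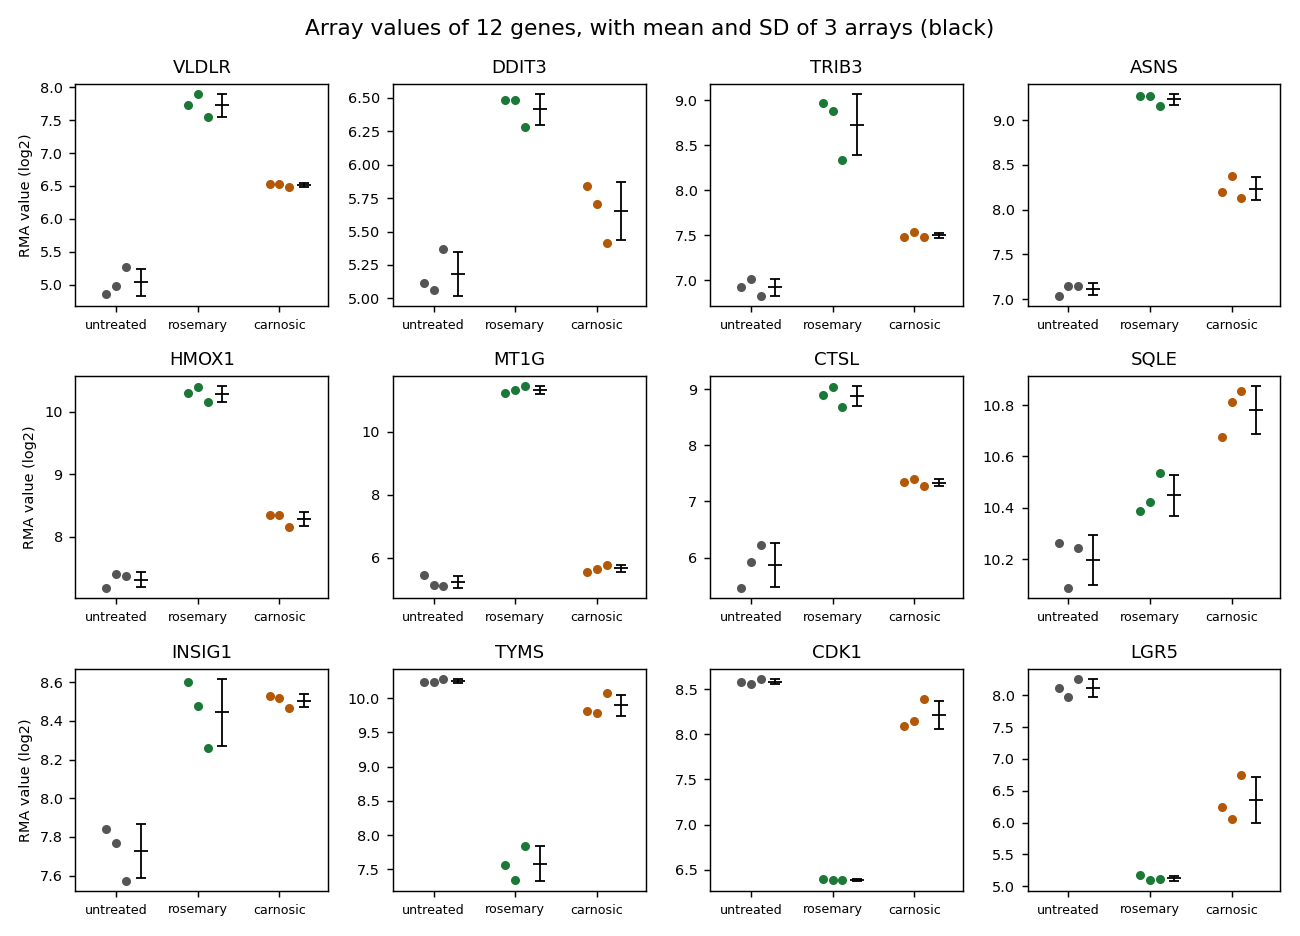
RMA values (log2) of 12 genes on each array of untreated, rosemary extract and carnosic acid cells. Coloured points are arrays, and black bars are the mean and SD of 3 arrays. MT1G rises to 11.32 with rosemary extract and stays at 5.66 with carnosic acid, while SQLE is highest with carnosic acid.

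Rosemary extract against untreated cells asked what the whole extract changed. The largest rises were in metallothioneins, small metal-binding proteins: MT1G went from 5.23 ± 0.20 to 11.32 ± 0.11 (log2, SD, n = 3), a 68.5-fold rise, and MT1F rose 29.6-fold. MT1H went from 3.31, under the dim limit, to 8.58, so no fold is given for it. All 6 tested metallothioneins were called higher (6 adjusted over the list alone), and camera called the list (adjusted p = 3.08e-07). Its adjusted p = 0.0692 with an estimated correlation. In every list called by camera here, that correlation gave the highest adjusted p of all the settings tried. Metallothionein genes are near-identical in sequence, so single members remain uncertain. Other large rises were in ABHD4 (8.27-fold), the lysosomal protease CTSL (8.04-fold), SPIRE1 (7.90-fold) and HMOX1, the haem-degrading enzyme (7.79-fold). The largest falls were in LGR5, a Wnt-responsive stem cell receptor (log2 change -2.99 ± 0.15, SE), the mitotic kinesins KIF20A (-2.68) and KIF11 (-2.37), TYMS (-2.66), MNS1 (-2.50), TOP2A (-2.44), NUSAP1 (-2.41) and OIP5 (-2.39).

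In the unfolded protein response lists most members rose with the extract. Of 9 tested members of the PERK-ATF4 arm 7 were called higher and 0 lower (7 adjusted over the list alone), with a mean log2 change of 1.15 (camera adjusted p = 7.60e-05). VLDLR, a lipoprotein receptor, rose by 2.68 ± 0.12 (log2, SE), SESN2 by 2.02, DDIT4 by 1.83 and the pseudokinase TRIB3 by 1.81. DDIT3, which encodes CHOP, rose by 1.23 ± 0.13, and ATF4 itself by 0.21 ± 0.06 (adjusted p = 0.0169). The call of ATF4 was lost under cyclic loess (adjusted p = 0.132), without untreated replicate 3 (0.0594) and without rosemary extract replicate 1 (0.0607). Of 15 tested ER chaperone and degradation genes 10 were called higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.00170). SEL1L rose by 1.03, HYOU1 by 0.80 (dimmer row 0.14), the sensor ATF6 by 0.75, DERL1 by 0.74 and XBP1 by 0.49. The 2 lower members, CALR (-0.094, adjusted p = 0.0498) and CRELD2 (-0.26, adjusted p = 0.0484), lay near the threshold and were named after their values were seen. Without any 1 of the 9 arrays the lower count was 0 or 1. Both lists had an adjusted p = 0.0982 with an estimated correlation. HSPA5 and HERPUD1 had no named row here.

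Most genes that supply and charge amino acids rose with the extract. All 12 aminoacyl-tRNA synthetases were called higher (12 adjusted over the list alone), with a median log2 change of 0.65 (camera adjusted p = 3.15e-09). WARS1 rose 2.93-fold (log2 1.55, whose dimmer row gave 0.49), SARS1 2.38-fold and GARS1 2.33-fold. Of 8 amino acid synthesis and transport genes 6 were called higher (6 adjusted over the list alone, camera adjusted p = 0.000383), with ASNS, asparagine synthetase, up by 2.12 ± 0.08 (log2, SE), CTH by 1.70 and PSAT1 by 1.23. Of 10 NRF2 targets 9 were called higher (9 adjusted over the list alone, camera adjusted p = 7.55e-08), led by HMOX1, the sulfiredoxin SRXN1 (2.41), PGD (1.17) and GSR (1.16). Of 15 autophagy and lysosome genes 12 were called higher (13 adjusted over the list alone, camera adjusted p = 9.53e-07), among them CTSD (0.90), SQSTM1 (1.21) and MAP1LC3B (1.21). Each of these 4 lists had an adjusted p = 0.0982 with an estimated correlation.

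All but 1 of the 38 tested genes of DNA replication and mitosis were called lower with the extract. Of 20 G1/S and replication genes 19 were called lower (19 adjusted over the list alone), with a median log2 change of -1.56. The exception, a gene outside the naming rule, was CCND1 (-0.13, adjusted p = 0.132). PCNA, the sliding clamp of DNA polymerase, fell by 1.52 ± 0.06 (log2, SE), as did the nucleotide-making enzyme RRM2 (-1.82) and the helicase subunit MCM3 (-1.77). All 18 tested G2/M genes were called lower (18 adjusted over the list alone), with a median of -1.77, including the kinase CDK1 (-2.20) and cyclin CCNA2 (-1.91). Camera gave adjusted p = 1.96e-16 and 9.55e-19 for the 2 lists. These became adjusted p = 0.128 and p = 0.122 with an estimated correlation. Ribosomal protein genes were lower in 6 of 15 members and higher in 0 (9 lower and 1 higher adjusted over the list alone), with RPS19 at -0.49 (camera adjusted p = 0.0401). The lower count was 3 without untreated replicate 3 or rosemary extract replicate 1, and 1 member was higher without untreated replicate 3 or carnosic acid replicate 3. The list call was lost without untreated replicate 3 (adjusted p = 0.109), without rosemary extract replicate 1 (adjusted p = 0.0765) and with an estimated correlation (adjusted p = 0.686).

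Sterol genes went both ways with the extract. Of 13 cholesterol synthesis enzymes 4 were called higher and 4 lower (5 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.994). The lower count was 2 without untreated replicate 1, untreated replicate 3 or rosemary extract replicate 2. The list's median (0.08) and mean (-0.048) differed in sign. MSMO1 rose by 0.77 ± 0.09 (log2, SE), IDI1 by 0.32 and SQLE, squalene epoxidase, by 0.25, while ACAT2 (-1.36) and EBP (-0.36) fell. HMGCS1 rose by 0.20, a call lost under cyclic loess (adjusted p = 0.150), under median centring (0.0545), and without untreated replicate 2 (0.0508), untreated replicate 3 (0.0563), rosemary extract replicate 1 (0.0518) or rosemary extract replicate 2 (0.0985). Of 6 sterol-sensing genes 4 were called higher (4 adjusted over the list alone, camera adjusted p = 0.134, fry 0.00559), with INSIG1 up by 0.72 and STARD4 by 0.64. The other 2, SREBF2 (0.24) and INSIG2 (0.29), both lost their calls without untreated replicate 2 (adjusted p = 0.0779 and 0.0791), rosemary extract replicate 1 (0.0726 and 0.1002) or rosemary extract replicate 2 (0.0707 and 0.0612). SREBF2 lost it also without untreated replicate 3 (0.0636) and under cyclic loess (0.0702), and INSIG2 without untreated replicate 1 (0.0710) and in a fit to the 6 arrays compared (0.0513). SREBF1 did not pass (0.026, adjusted p = 0.855), and its sign turned under cyclic loess (-0.011), under median centring (-0.0066) and without untreated replicate 3 (-0.0092). ABCA1 had no named row here.

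The fit called 4256 genes, 2439 higher and 1817 lower, of which 570 changed at least 2-fold. Cyclic loess gave 2258 higher and 2113 lower, and median centring 2256 and 2118. Values of the groups did not overlap for 46.7% of the genes tested, where chance gives 10%. When all rows of the array were tested, named or not, 7230 were called.

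**Figure D2:**
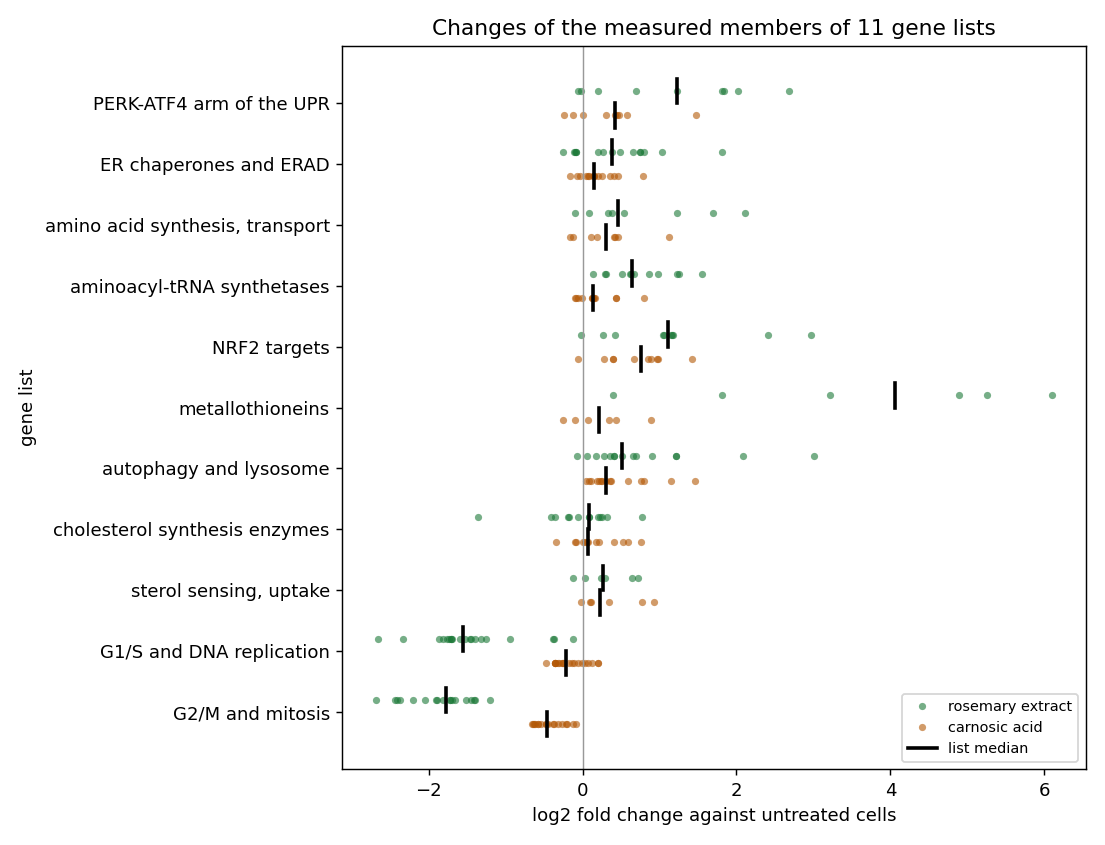
Log2 fold change against untreated cells (horizontal axis) of the tested members of 11 gene lists (vertical axis), for rosemary extract (green) and carnosic acid (orange), with black ticks at the list medians. The G2/M median is -1.77 with rosemary extract and -0.47 with carnosic acid.

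Carnosic acid against untreated cells asked what the single compound changed. CEACAM5, the carcinoembryonic antigen, rose from 7.19 ± 0.43 to 9.40 ± 0.25 (log2, SD, n = 3), a 4.65-fold rise. ABHD4 rose 4.32-fold, the monoamine oxidase MAOB 4.29-fold, SCEL 3.53-fold, VSIG10L and GPAT3 3.31-fold each, APCDD1L-DT 3.23-fold and the hypoxia-inducible factor EPAS1 3.19-fold. Endothelin EDN1 fell by 1.94 ± 0.14 (log2, SE), and so did LGR5 (-1.76), the thrombin receptor F2R (-1.42), TSPAN8 (-1.23), ROR1 (-1.18), VGLL1 (-1.17), the water channel AQP5 (-1.15) and HSD17B2 (-1.08). Of 10 NRF2 targets 9 were called higher (9 adjusted over the list alone, camera adjusted p = 5.24e-09). SRXN1 rose by 1.42, UGDH by 0.97, HMOX1 by 0.97, GSR by 0.89 and PGD by 0.84. Of 15 autophagy and lysosome genes 10 were called higher (11 adjusted over the list alone, camera adjusted p = 1.24e-06), with CTSL up by 1.47, GABARAPL1 by 1.14 and CTSD by 0.76. Both lists had an adjusted p = 0.165 with an estimated correlation.

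Some sterol genes rose with carnosic acid, and most did not pass. Of 13 cholesterol synthesis enzymes 4 were called higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0410). MSMO1 rose by 0.76 ± 0.09 (log2, SE), SQLE by 0.58 ± 0.07, IDI1 by 0.53 and HMGCS1 by 0.41, and ACAT2 fell by 0.35 (adjusted p = 0.0308, named after its values were seen), a call lost without untreated replicate 1 or 3 or carnosic acid replicate 1 or 2. Of 6 sterol-sensing genes 3 were called higher (3 adjusted over the list alone, camera adjusted p = 0.0155): STARD4 (0.92), INSIG1 (0.78) and SREBF2 (0.34). SREBF1 did not pass (0.10, adjusted p = 0.483). The lists had adjusted p = 0.535 and p = 0.381 with an estimated correlation. The cholesterol synthesis call was also lost under cyclic loess (adjusted p = 0.119), with the mean of a gene's rows (0.0620), without untreated replicate 2 (0.0716) and without carnosic acid replicate 3 (0.185). With the dimmer 50% of genes left out, the adjusted p-values of the 2 lists were 0.170 and 0.0629.

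Part of the unfolded protein response lists rose with carnosic acid. In the PERK-ATF4 arm 6 of 9 members were called higher and 0 lower (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0340). VLDLR rose by 1.48 ± 0.12 (log2, SE), TRIB3 by 0.58, DDIT3 by 0.47 and DDIT4 by 0.42, while ATF4 (-0.12, adjusted p = 0.188) did not pass. DDIT3's call was lost without untreated replicate 1 (adjusted p = 0.0743), untreated replicate 2 (0.0836), carnosic acid replicate 1 (0.0986) or carnosic acid replicate 2 (0.0633). Without carnosic acid replicate 2 the arm's count was 3 higher and 1 lower. Among 15 ER chaperone and degradation genes 6 were called higher (6 adjusted over the list alone, camera adjusted p = 0.00896), including the sensor ERN1 (0.79), DERL1 (0.46) and HYOU1 (0.41, whose dimmer row gave -0.023). XBP1 did not pass (0.085, adjusted p = 0.391). For the 2 lists adjusted p = 0.381 and p = 0.270 with an estimated correlation. The PERK-ATF4 call was lost under cyclic loess (adjusted p = 0.0511) and without untreated replicate 3 (0.0527), carnosic acid replicate 1 (0.0621) or carnosic acid replicate 2 (0.0600). Leaving out the dimmer 50% of genes gave adjusted p-values of 0.0640 and 0.0563.

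Amino acid genes were called higher in 4 of 8 members (5 adjusted over the list alone, camera adjusted p = 0.0115), with ASNS up by 1.12 ± 0.08 (log2, SE). Aminoacyl-tRNA synthetases were called higher in 4 of 12 (6 adjusted over the list alone, camera adjusted p = 0.0340), with WARS1 up by 0.80 (dimmer row 0.14). With an estimated correlation these became adjusted p = 0.381 and p = 0.537. The synthetase call was lost under cyclic loess (adjusted p = 0.294), under median centring (0.0742), with the dimmer 50% left out (0.145), and without untreated replicate 2 (0.0609) or carnosic acid replicate 1 (0.0888). Metallothioneins were not called as a list (camera adjusted p = 0.358), with 3 of 6 members higher (3 adjusted over the list alone): MT1F (0.89), MT1G (0.43) and MT2A (0.34). The call of MT1F was lost without untreated replicate 2 (adjusted p = 0.0901), carnosic acid replicate 1 (0.129) or carnosic acid replicate 2 (0.0596). That of MT1G was lost without untreated replicate 2 (0.0568), untreated replicate 3 (0.0502) or carnosic acid replicate 3 (0.0529). That of MT2A was lost under cyclic loess (0.0869), under median centring (0.0514) and without untreated replicate 2 (0.0872), untreated replicate 3 (0.0842), carnosic acid replicate 1 (0.0891) or carnosic acid replicate 2 (0.0734).

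Of 18 G2/M genes 12 were called lower (16 adjusted over the list alone), with the survivin gene BIRC5 at -0.66 ± 0.10 (log2, SE) and the cyclin CCNB1 at -0.57 (camera adjusted p = 5.24e-09). Of 20 G1/S and replication genes 6 were called lower (9 adjusted over the list alone, camera adjusted p = 0.0115), with PCNA at -0.26. That count was 2 without untreated replicate 1, 1 without untreated replicate 2, 3 without rosemary extract replicate 1, 1 without carnosic acid replicate 1 and 2 without carnosic acid replicate 2. The lists had adjusted p = 0.381 and p = 0.572 with an estimated correlation, and fry gave an adjusted p of 0.223 for the G1/S list. Without carnosic acid replicate 1 its camera adjusted p = 0.0590. Ribosomal proteins were lower in 6 of 15 (7 adjusted over the list alone, camera adjusted p = 0.000953), with RPL19 at -0.37 (dimmer row -1.06), and respiratory chain genes in 3 of 8 (4 adjusted over the list alone, camera adjusted p = 0.0307), with COX4I1 at -0.25. NF-kB targets and chemokines were higher in 3 of 7 (3 adjusted over the list alone, camera adjusted p = 0.0405): CXCL8 by 0.80, ICAM1 by 0.51 and IRF1 by 0.44. These 3 lists had adjusted p = 0.434, p = 0.381 and p = 0.414 with an estimated correlation. The respiratory call was lost without carnosic acid replicate 1 (adjusted p = 0.0621). The calls of ICAM1 (0.0503) and of the NF-kB list (0.124) were lost without that array too, and the latter also without untreated replicate 2 (0.0716) and with the dimmer 50% left out (0.116).

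The fit called 2123 genes, 1440 higher and 683 lower, of which 103 changed at least 2-fold, 87 higher and 16 lower. The split depended on scaling: median centring gave 1207 higher and 1098 lower, and cyclic loess 1245 and 1022. Without carnosic acid replicate 1 the count was 1385, with 1018 higher and 367 lower. Values of the groups did not overlap for 32.8% of the genes tested, where chance gives 10%.

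Rosemary extract and carnosic acid were then compared directly. Metallothioneins differed most: MT1G was 50.8-fold higher with the extract, MT1F 16.0-fold and MT1X 8.87-fold, while MT1H lay at 8.58 with the extract and under the dim limit with carnosic acid (3.21), and all 6 members were called higher (6 adjusted over the list alone, camera adjusted p = 3.91e-13, and adjusted p = 0.0127 with an estimated correlation). CLGN, an ER chaperone, was 5.57-fold higher. Replication and mitosis genes were lower with the extract in 19 of 20 and 18 of 18 members (19 and 18 adjusted over the list alone), with TYMS lower by -2.30 ± 0.11 (log2 difference, SE), KIF11 by -1.99, CDK1 by -1.83 and PCNA by -1.27 (camera adjusted p = 8.91e-28 and 1.00e-28). E2F8 (-2.18), ADGRF1 (-2.17), MNS1 (-2.12) and the replication factor TICRR (-2.11) were also lower. Both lists had an adjusted p = 0.0700 with an estimated correlation.

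PERK-ATF4 genes were higher with the extract than with carnosic acid in 7 of 9 members (8 adjusted over the list alone, camera adjusted p = 1.10e-07). SESN2 was higher by 1.58 ± 0.13 (log2 difference, SE), DDIT4 by 1.41, TRIB3 by 1.23, VLDLR by 1.21 and DDIT3 by 0.76. Of 15 ER genes 8 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00114), with ERN1 higher by 1.02 and XBP1 by 0.40. The lower member, CALR (-0.13, adjusted p = 0.0186), was named after its values were seen and lost its call without rosemary extract replicate 1 or 2 or carnosic acid replicate 2 or 3. All 12 aminoacyl-tRNA synthetases were higher (12 adjusted over the list alone, camera adjusted p = 1.55e-15), with AARS1 at 0.83. For these 3 lists adjusted p = 0.0635, p = 0.0719 and p = 0.0635 with an estimated correlation. Amino acid genes were higher in 3 of 8 (5 adjusted over the list alone, camera adjusted p = 2.48e-05), CTH by 1.28 and PSAT1 by 0.78. NRF2 targets were higher in 6 of 10 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.99e-05), HMOX1 by 1.99. Autophagy and lysosome genes were higher in 8 of 15 (8 adjusted over the list alone, camera adjusted p = 0.000143), CTSL by 1.54, and in 5 without rosemary extract replicate 1 or 2 or carnosic acid replicate 1 or 3. Their adjusted p-values with an estimated correlation were p = 0.0700, p = 0.09998 and p = 0.09998. p53 targets were higher in 2 of 5 (3 adjusted over the list alone, camera adjusted p = 0.0270): GDF15 by 1.26 and RRM2B by 0.49. That call was lost without rosemary extract replicate 1 (adjusted p = 0.0670), without carnosic acid replicate 2 (0.113) and with an estimated correlation (adjusted p = 0.251).

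Cholesterol synthesis enzymes were lower with the extract than with carnosic acid in 5 of 13 members and higher in 0 (6 lower adjusted over the list alone), with a mean log2 difference of -0.22 (camera adjusted p = 0.00250). ACAT2 differed by -1.02 ± 0.10 (log2, SE), EBP by -0.37, DHCR7 by -0.36, SQLE by -0.33 and HMGCS1 by -0.21. The list had an adjusted p = 0.271 with an estimated correlation. The call of HMGCS1 was lost under median centring (adjusted p = 0.0579) and without rosemary extract replicate 1 (0.117), 2 (0.0565) or 3 (0.103) or carnosic acid replicate 1 (0.119) or 2 (0.125). Sterol-sensing genes were not called as a list (camera adjusted p = 0.482), with 1 of 6 members, STARD4, lower (-0.29, adjusted p = 0.0495, and 0 members adjusted over the list alone). STARD4's call was lost without each array in turn except rosemary extract replicate 1 and carnosic acid replicate 2 (adjusted p = 0.0582 to 0.156), and under median centring (0.0524), array weights (0.0555), no dim filter (0.0683), eBayes without a trend (0.0644) and a fit to the 6 arrays compared (0.0849). INSIG1 did not pass (-0.059, adjusted p = 0.761), and gave 0.034 without rosemary extract replicate 3. The direct comparison called 1933 genes, 920 higher and 1013 lower with the extract (1020 and 996 under median centring, 1036 and 929 without rosemary extract replicate 3), and 214 of them differed at least 2-fold, 41 higher and 173 lower. The count of higher genes was 551 without rosemary extract replicate 1, 533 without rosemary extract replicate 2 and 612 without carnosic acid replicate 2.

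The treatments' calls overlapped. Both raised 1327 genes and lowered 567, where independent lists would share 315 and 111. Simulated unchanged groups, in which almost nothing is called, shared 0.01 on average, which does not bear on the overlap of lists that hold real changes. Median centring gave 1111 raised and 878 lowered by both, and cyclic loess 1139 and 874. Without carnosic acid replicate 1 the shared total of 1894 was 1251, with 927 raised and 324 lowered. MAOB rose by 2.10 with each (log2; difference -0.002 ± 0.12, SE, adjusted p = 0.997), and CEACAM5, LGR5 and CD68 moved in the same direction with both. Fold changes of the treatments correlated across genes, which are not independent replicates (r = 0.79, rho = 0.80, against r = 0.50 ± 0.008 simulated). Their covariance was 0.104 against 0.00548 simulated, a difference of 0.0988. The simulated groups hold no real changes, so the simulated r of 0.50 is not the part of 0.79 owed to shared untreated arrays. Shared control noise adds the same covariance whether or not genes change, so the covariance comparison carries over. Part of the excess overlap may come from the shared untreated arrays, which are too few to split. Of the 1894 shared calls 1611 (85.1%) were larger with the extract. The direct comparison called 804 of them, 782 larger with the extract and 22 larger with carnosic acid.

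**Figure D3:**
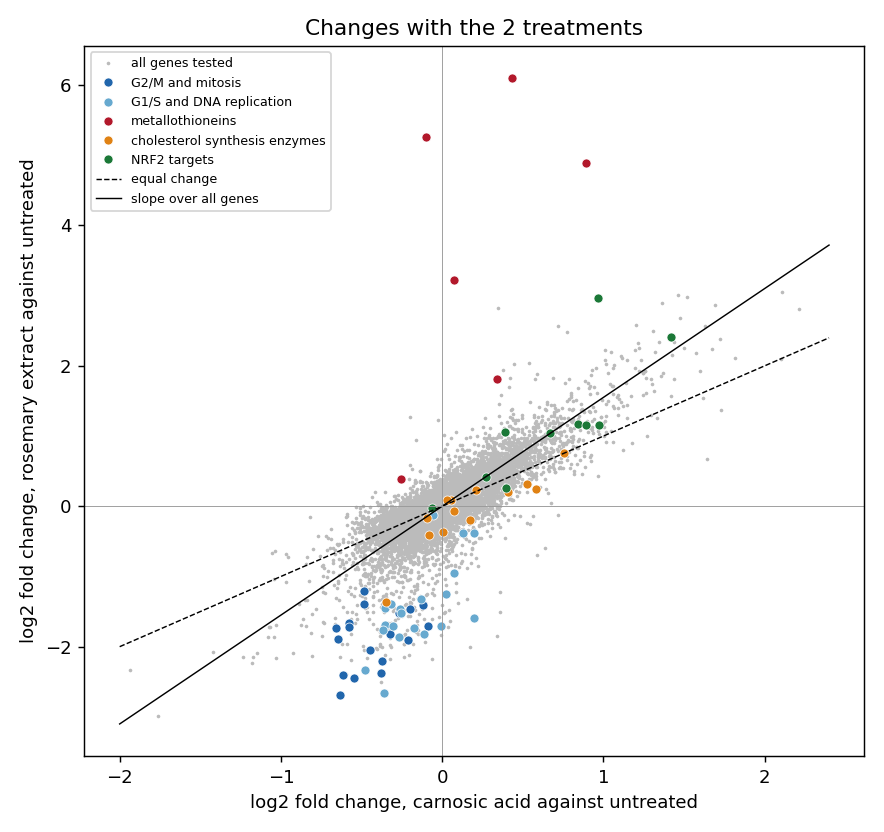
Log2 fold change with rosemary extract (vertical axis) against that with carnosic acid (horizontal axis) for the 11163 genes tested, with 5 gene lists coloured. The dashed line marks equal change and the solid line the slope over all genes after removing shared control noise, 1.55. The 6 tested metallothioneins lie above both lines, by 0.65 to 5.67 (log2) over equal change, and the 38 replication and mitosis genes lie below both.

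Several lists with no camera call for a treatment held genes moving both ways. Of 12 fatty acid synthesis genes the extract raised 4 and lowered 3 (4 and 4 adjusted over the list alone, camera adjusted p = 0.929), with ACSS2 up by 1.45 ± 0.10 (log2, SE), ELOVL1 by 1.12 and FASN down by 0.77. Its median (-0.15) and mean (0.11) differed in sign. Carnosic acid raised 3 and lowered 0 (3 and 1 adjusted over the list alone, camera adjusted p = 0.358), among them SCD (0.75, dimmer row 0.11), and lowered 1 without carnosic acid replicate 3. Of 10 Wnt targets of the crypt the extract lowered LGR5 and MYC (-0.72) and raised AXIN2 (1.15) and NKD1 (0.38). Carnosic acid lowered LGR5, MYC (-0.35) and SP5 (-0.31) and raised AXIN2 (0.66). The call of SP5 was lost without each array in turn except untreated replicate 3 (adjusted p = 0.0509 to 0.158), under cyclic loess (0.0668), without the dim filter (0.0547) and in a fit to the 6 arrays compared (0.0780). The Wnt counts were the same adjusted over the list alone. Camera adjusted p-values for the Wnt list were 0.651 and 0.164. Fry called it for both treatments (adjusted p = 0.00597 and 0.00567). It also called the fatty acid (0.00499 and 0.00230) and glycolysis and hypoxia lists (0.000392 and 0.0311) for both. Of 17 ERK output and immediate early genes the extract raised 7 and lowered 4, with DUSP5 up by 1.71 (dimmer row 0.49) and FOS at -0.82 (dimmer row -1.46), and carnosic acid raised 6 and lowered 3 (7 and 4 for each adjusted over the list alone, camera adjusted p = 0.720 and 0.440). Of 11 glycolysis and hypoxia genes the extract raised 4 and lowered 2, with NDRG1 up by 2.58 and VEGFA by 1.45, and carnosic acid raised 3 and lowered 1 (4 and 2, and 4 and 1, adjusted over the list alone, camera adjusted p = 0.548 and 0.444). With the extract the medians of the ERK (-0.028) and hypoxia lists (-0.0034) were negative and their means (0.20 and 0.39) positive. The lower hypoxia count with carnosic acid was 0 without untreated replicate 1 or 3 or carnosic acid replicate 1 or 2.

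Of 8 heat shock genes the extract raised 2 and lowered 4, with BAG3 up by 0.76 and HSPB1 down by 0.92 (log2), and carnosic acid raised 2 and lowered 2 (2 and 4, and 4 and 2, adjusted over the list alone, camera adjusted p = 0.773 and 0.761). With carnosic acid that list's median (-0.025) was negative while camera pointed up. With the extract the heat shock counts were 1 higher without untreated replicate 1 or 2 or any rosemary extract array, and 2 lower without untreated replicate 1, untreated replicate 3 or rosemary extract replicate 1. With carnosic acid the higher count was 1 without untreated replicate 1 or any carnosic acid array, where HSPA1B (0.20) lost its call (adjusted p = 0.0630 to 0.0920), as it did under cyclic loess (0.0845), under median centring (0.0764), with eBayes without a trend (0.0913) and in a fit to the 6 arrays compared (0.0552). The lower count with carnosic acid was 1 without untreated replicate 1 or rosemary extract replicate 2, and 0 without untreated replicate 3, rosemary extract replicate 1, or carnosic acid replicate 1 or 2. Of 11 BCL2 family genes 3 rose and 1 fell with the extract and 2 rose with carnosic acid, BCL2L1 by 0.41 and 0.29 (3 and 1, and 2 and 1, adjusted over the list alone, camera adjusted p = 0.773 and 0.510). Of 5 p53 targets the extract raised 2, led by GDF15 (1.23), and lowered SESN1 (-0.52), which carnosic acid also lowered (-0.49; camera adjusted p = 0.349 and 0.510, with the same counts over the list alone). The SESN1 call with the extract was lost without untreated replicate 3 (adjusted p = 0.0660), rosemary extract replicate 2 (0.0585) or rosemary extract replicate 3 (0.0587). That with carnosic acid was lost without untreated replicate 2 (0.0851) or 3 (0.131), rosemary extract replicate 2 (0.0594), or carnosic acid replicate 1 (0.0975) or 2 (0.128), and under cyclic loess (0.0533). LXR targets had 3 tested members, of which the extract lowered MYLIP (-0.29) and carnosic acid raised LPCAT3 by 0.29 (camera adjusted p = 0.773 and 0.421, with the same counts over the list alone). MYLIP's call was lost without untreated replicate 1 (adjusted p = 0.0709) or 3 (0.108) or rosemary extract replicate 2 (0.138) or 3 (0.0629), and 1 LXR target was higher with the extract without untreated replicate 3. For the BCL2 family the lower count with the extract was 0 without untreated replicate 2 or rosemary extract replicate 1 or 2, the higher count with carnosic acid was 1 without each array in turn except rosemary extract replicate 1, and 1 gene was lower with it without untreated replicate 2. Respiratory chain genes were lower in 5 of 8 with the extract (5 adjusted over the list alone, 3 without untreated replicate 1 or rosemary extract replicate 1 or 2, camera adjusted p = 0.131), and NF-kB targets higher in 3 of 7 (3 adjusted over the list alone, camera adjusted p = 0.129). Fry called both lists for the extract (adjusted p = 0.00789 and 0.00508). It also called p53 targets for the extract (0.00897) and LXR targets for carnosic acid (0.0430). None of 6 interferon-stimulated genes was called for either treatment by limma (0 and 1 at an unadjusted p under 0.05, camera adjusted p = 0.548 and 0.358, fry 0.159 and 0.223). The single xenobiotic gene tested, TIPARP, did not pass with the extract (-0.05, adjusted p = 0.602) or carnosic acid (0.07, adjusted p = 0.531).

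Camera called no cell type list for either treatment, while fry called the leukocyte list for both (0.000542 with the extract, 0.0118 with carnosic acid) and the enterocyte list for carnosic acid (0.0223). Of 9 absorptive enterocyte markers 2 were called higher and 2 lower with the extract, and 2 and 1 with carnosic acid (the same counts over the list alone). The higher count was 1 with the extract without untreated replicate 3 or rosemary extract replicate 1, and 1 with carnosic acid without untreated replicate 1 or 2 or carnosic acid replicate 3. KRT20 rose by 0.77 with the extract and 0.88 with carnosic acid, and the microvillus protein VIL1 fell by 1.29 and 0.35 (log2; camera adjusted p = 0.867 and 0.583). Of 5 goblet cell markers 2 were called higher and 1 lower with the extract, and 1 and 0 with carnosic acid (the same counts over the list alone). SPDEF rose by 0.71 and 0.92, AGR2 rose by 0.50 with the extract and gave -0.13 with carnosic acid (adjusted p = 0.517), and TFF3 was lower with the extract (-0.26, adjusted p = 0.0497), a call lost without each array in turn except untreated replicate 3 (adjusted p = 0.0554 to 0.182), without the dim filter (0.0611), with robust eBayes (0.0505) and in a fit to the 6 arrays compared (0.0790). For the goblet list camera adjusted p = 0.651 and 0.761. With carnosic acid the medians of the goblet (-0.12) and leukocyte lists (-0.055) were negative and their means (0.13 and 0.16) positive. Of 5 leukocyte markers CD68, which also encodes a lysosomal membrane protein, rose by 1.89 and 1.24, and the other 4 did not pass (camera adjusted p = 0.572 and 0.592), apart from 1 lower with carnosic acid without carnosic acid replicate 2. No marker of the enteroendocrine list (4 tested), the hepatocyte list (4 tested) or the fibroblast list (2 tested) was called for either treatment by limma. At an unadjusted p under 0.05 the count was 1, the hepatocyte marker APOA1 with carnosic acid (-0.28), with camera adjusted p = 0.650 and 0.476 for enteroendocrine and 0.650 and 0.604 for hepatocyte markers (fry 0.168 and 0.223, and 0.150 and 0.499). Leaving out untreated replicate 3 gave 1 lower hepatocyte marker with the extract, and leaving out carnosic acid replicate 2 gave 1 lower fibroblast marker with carnosic acid.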

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

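The array scaling and proportional-response tests and the weighing of shared metallothionein signal were chosen only after the differences were seen. The tests of SLC30A1, of ACAT2 and of other splits were written before their results were seen.

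Gene lists whose change differed between the treatments by camera on the direct comparison are given as mean log2 difference, rosemary extract minus carnosic acid. Higher with the extract were metallothioneins (3.38), the PERK-ATF4 arm (0.78), aminoacyl-tRNA synthetases (0.58), NRF2 targets (0.49), amino acid genes (0.49), p53 targets (0.41), autophagy and lysosome genes (0.33) and ER chaperones (0.25). Lower were G2/M genes (-1.44), G1/S genes (-1.30) and cholesterol synthesis enzymes (-0.22). Of these 11 lists 1, metallothioneins, kept its call with an estimated correlation (adjusted p = 0.0127), and the other 10 had adjusted p from 0.0635 to 0.271. The metallothionein mean includes MT1H, which lay under the dim limit without the extract, so its exact size is uncertain.

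A set of 10 genes, named after their values were seen, was called lower with the extract, higher with carnosic acid and different between them. Their log2 differences were -1.28 for CEMIP, -1.24 for TRIM31, -0.84 for TPPP3, -0.65 for EPHB6, -0.62 for CEACAM1, -0.59 for THBS1, -0.53 for ICMT, -0.47 for RPUSD1, -0.42 for NRIP1 and -0.39 for IMPA2. The call of CEACAM1 with carnosic acid was lost without untreated replicate 1 (adjusted p = 0.0713), untreated replicate 2 (0.0624) or carnosic acid replicate 3 (0.0648). Leaving out each array in turn, 5 of the 10 genes kept all 3 calls and the opposite signs in every fit (CEMIP, EPHB6, NRIP1, TPPP3 and TRIM31). The others kept them in 6 of 9 fits (CEACAM1 and RPUSD1), 5 (THBS1), 3 (ICMT) and 1 (IMPA2). Among 18554 rows with no gene name here and a level above the dim limit, 3439 differed from untreated with the extract and 1273 with carnosic acid.

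Metallothioneins rose with rosemary extract far beyond their change with carnosic acid (medians 4.06 and 0.21, log2). The median difference stayed at 3.57 or above under cyclic loess and median centring. Array medians were already close after RMA, so these scalings could move it little. They speak only to offsets left between arrays, not to a shift hidden by RMA. A response in proportion to that of carnosic acid predicts 1.55 times its change, and the list's median exceeded that by 3.31, where 95% of 10000 random lists of matched expression lay between -0.21 and 0.17. The random lists hold unrelated genes, so their range is too narrow for genes that move together, and the metallothionein list was picked for this difference. Signal shared between near-identical family members stays open, because probe sequences were not used here: the smallest member difference was 0.65 (MT1E) and the largest 5.67. A wider metal response was not testable through the zinc exporter SLC30A1, which had 0 tested rows, and other constituents of the extract remain an untested explanation.

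Replication and mitosis genes, 38 in all, fell more with the extract (medians -1.70 and -0.31). Under cyclic loess and median centring the median difference was -1.30 or lower. As above, this speaks only to offsets left between arrays after RMA and does not exclude array scaling. Beyond a proportional response the median was lower by -1.21, outside the random range of -0.11 to 0.035, and 38 of 38 genes lay on that side. The random lists hold unrelated genes, while genes of these 2 lists move together (estimated correlations 0.63 and 0.74). The random range is therefore too narrow for them, and the 38 genes are not independent. The lists were also picked for this difference. A response that grows faster than in proportion, as with a stronger exposure, may still account for the larger fall, since doses are not given.

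Cholesterol synthesis enzymes were lower with the extract than with carnosic acid as a list by camera (list medians against untreated 0.084 and 0.073, median difference -0.21), with 5 of 13 members called. Camera's call held without ACAT2 (adjusted p = 0.0163, mean difference -0.16 over 12 genes), so that gene alone does not account for it. It also held under both scalings (largest adjusted p = 0.00301). Camera compares a list with the other genes, so median centring could hardly change that result. Array scaling is therefore not excluded. The median lay -0.37 from a proportional response (random range -0.16 to 0.094). That value cannot decide on such a response, because the list was picked for being lower with the extract and the random lists hold unrelated genes. Camera's adjusted p ranged from 0.000783 over the settings tried to 0.271 with an estimated correlation. That last setting changes both the correlation and the degrees of freedom, so whether the list stands out beyond genes that move together stays open.

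Other splits of the same arrays bear on the counts. With 6 arrays there are 10 splits, too few for a share under 0.05: in each comparison 1 split, the real one, gave as many calls. The real counts were 4017, 1785 and 1858 for rosemary extract, carnosic acid and their comparison, and the highest other split gave 0 by limma in each (105 to 515, 131 to 848 and 124 to 755 genes at an unadjusted p under 0.05). For the F test 1 of 100 drawn splits of the 280 possible, the real one with 3972 genes, gave as many, and the highest other gave 1982. The real split was always among the 100, so 1 of 100 is the smallest share this test can give. The other splits mix groups that differ, so they do not show what unchanged arrays would give. A batch that follows the groups would also pass this test.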

How the results depend on the processing

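No alternative was chosen after seeing the data. Counts of calls for rosemary extract, carnosic acid, their comparison, the F test and both treatments alike stayed within 1.5 times under the settings tried, except as follows. A 2-fold minimum gave 570, 103, 214, 577 and 96. Testing all rows, more than the named genes, gave 7230 for the extract and 6141 for the F test. Leaving out 1 array gave 1385 to 2124 for carnosic acid and 1251 to 1893 for both alike, lowest without carnosic acid replicate 1. The correlation was 0.819 with the dimmer 50% left out, 0.747 over all rows and 0.751 to 0.819 without 1 array. The cause was not tested.

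Camera called 10, 13 and 11 lists for the extract, carnosic acid and their comparison. With an estimated correlation it called 0, 0 and 1 (9, 3 and 9 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 18, 18 and 15. For carnosic acid 7 lists were called with the dimmer 50% left out and 8 to 13 without 1 array. With that correlation adjusted p was 0.0982 for both unfolded protein response lists with the extract. With carnosic acid it was 0.381 (PERK-ATF4), 0.270 (ER), 0.535 (cholesterol synthesis) and 0.381 (sterol sensing), and between treatments 0.0635, 0.0719 and 0.271 for the first 3. The estimated correlation of the ER list was only 0.028. Its lost calls therefore cannot be put down to genes moving together alone, since the degrees of freedom change too. With the dimmer 50% left out the carnosic acid lists had 0.0640, 0.0563, 0.170 and 0.0629. Cyclic loess gave 0.0511 for PERK-ATF4 and 0.119 for cholesterol synthesis, and the mean of a gene's rows 0.0620 for the latter. Without 1 array these 2 ranged over 0.0139 to 0.0621 and 0.0125 to 0.185. Fry called sterol sensing with the extract (0.00559) and turned the direction of fatty acid synthesis (0.00499). The cause was not tested.

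Over 282 named gene changes, 2751 of 2813 settings and 2376 of 2538 fits without 1 array kept direction and call, and 60 and 159 lost the call. Uncalled values near 0 turned sign: SREBF1 with the extract (-0.011 under cyclic loess, -0.0066 under median centring, -0.0092 to 0.051 without 1 array, lowest without untreated replicate 3), and between treatments SREBF1 (-0.17 to 0.0085, highest without carnosic acid replicate 3) and INSIG1 (-0.14 to 0.034, highest without rosemary extract replicate 3). The replicate block, with the number as a term, gave 4226, 2194, 1947, 3978 and 1956 calls, and ended the calls of TFF3 with the extract (adjusted p = 0.0645) and of SP5 (0.0536), NARS1 (0.0628) and HSPD1 (0.0560) with carnosic acid, and no other named gene or list. Its numbers do not pair the samples: 3 of 9 same-numbered pairs correlated over 0.1 (-0.22 to 0.24), and 4 of 9 arrays correlated best with their own number. Some unlike-numbered pairs lay further from 0. Rosemary extract replicate 3 with carnosic acid replicate 2 gave 0.28, and untreated replicate 3 with carnosic acid replicate 2 gave -0.36. Structure that crosses the groups under other numbers was not modelled. Without detection calls, values near the dim limit of 4.50 remain the least certain.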

Other observations

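No test in this part was chosen after its result was seen. Several lists that camera did not call in the direct comparison still held single genes that differed between the treatments by limma's adjusted p. Of 11 glycolysis and hypoxia genes 3 were higher with rosemary extract than with carnosic acid and 1 lower (camera adjusted p = 0.364, fry 0.00517). NDRG1 was higher by 1.38 ± 0.13 (log2, SE, n = 3 per group), the angiogenic factor VEGFA by 1.10 and ADM by 0.64, while the hexokinase HK2 was lower (-0.51). Of 12 fatty acid synthesis genes 2 were higher and 5 lower (camera adjusted p = 0.461), or 3 lower without rosemary extract replicate 1 or 2 or carnosic acid replicate 2 or 3. Fatty acid synthase, FASN, was lower (-0.62 ± 0.07), as was ACLY (-0.29), whereas ACSS2 was higher by 0.59 and ELOVL1 by 0.33. Of 17 ERK output genes 2 were higher and 2 lower: the phosphatases DUSP5 (0.80) and DUSP1 (0.43), and the immediate early genes FOS (-0.56) and FOSB (-0.49) (camera adjusted p = 0.856). Without rosemary extract replicate 3 there were 4 higher.

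Markers of differentiated intestinal cells differed for single genes. Among 9 absorptive enterocyte markers VIL1 (-0.94 ± 0.07, log2 difference, SE) and CEACAM1 (-0.62) were lower with rosemary extract than with carnosic acid (camera adjusted p = 0.257, fry 0.00419). Among 5 goblet cell markers AGR2, an ER-resident protein disulfide isomerase, was higher by 0.63 (camera adjusted p = 0.968). Of 10 Wnt targets 2 were higher and 2 lower (camera adjusted p = 0.896). LGR5 (-1.23) and MYC (-0.36) were lower, AXIN2 was higher by 0.49 and NKD1 by 0.37, the last a call lost without rosemary extract replicate 2 (adjusted p = 0.0507). The lysosomal protein CD68 was higher by 0.65.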
